A study of Prunus sibirica with 30 samples.

How the data were processed

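Gene expression was measured by RNA sequencing in flowers of Prunus sibirica, the Siberian apricot, at bloom. The labels name the pistil as the tissue, while the protocol text speaks of flowers and flower buds. Clone 453, labelled CR and described as strongly frost resistant, was compared with clone 371, labelled NC and described as weakly frost resistant. Flowers of both clones were held at -4 °C for 0 h, 15 min, 30 min, 1 h or 2 h. No group was held for the same times at another temperature, so cold cannot be told apart from elapsed time or handling. Each of the 10 groups held 3 libraries, 30 in all. The labels do not say whether the 3 replicates of a group came from separate trees, so p-values measure the spread between these samples, which may be partly technical.

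The values used here are FPKM (fragments per kilobase of gene length, scaled by library size) that the authors deposited, 1 column per library. HISAT2, Picard, SAMtools 0.1.18 and GATK are named in the submitters' processing notes, with no role or order. The read counter, the annotation and the genome build are not given in the sources used here. The table used here held 143 complete genes in descending order of their mean FPKM, from 3835 to 594, and 1 incomplete last entry was left out. Less abundant genes were not analysed here. Gene names are the best Swiss-Prot match in the deposited description: 137 of the 143 genes had such a name and 6 had none. A further limit is that 27 genes shared their name with another gene, so reads could have been split between near-identical copies. Coordinates are those of the deposited table, on chromosomes 1 to 8 of a build that is not named.

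Multiplied by gene length, the FPKM values of each library were whole multiples of a single step for 4290 of 4290 values (tolerance 1e-06), which gave the number of reads behind each value. These ranged from 2481 to 195004 reads, so the counting error of the lowest value was 2.01%, and the 143 genes together took 1731103 to 3544827 reads per library, 9.75% to 20.5% of the divisor that the step implies. That divisor was a whole number in 0 of 30 libraries. It was therefore a scaled library size and not a plain total, and how it was set is not given in the sources used here. FPKM values are shares of a total, so a change in other abundant transcripts moves every value of a library together.

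The tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend. A single model with 10 group means was fitted to all 30 libraries, which gave 28.1 moderated degrees of freedom. A filter asked for an FPKM of at least 1 in at least 3 libraries and removed 0 genes, so it changed nothing. Each of 4 times was compared with 0 h within each clone and CR was compared with NC at each of 5 times. An F test over the 4 times was run for each clone, and another for the clone by time interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each result, with a threshold of 0.05. Changes are differences of log2(FPKM + 1), with standard errors (SE) from the model, and levels are mean FPKM ± SD with n = 3. Because the median of all genes moved in several comparisons, every test was repeated after each library was centred on its median, and such values are called relative, or relative to the median. The shift this takes out of a comparison is the mean difference between the library medians, which is not the same as the median of the gene changes.

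Before the data were examined, 32 gene lists were fixed, and their members were found by name or protein domain. Ribosomal proteins had 69 members, photosynthesis 8, membrane transport 5 (all aquaporins), household genes 5 and late embryogenesis abundant or cold-regulated proteins 3. Heat shock proteins, antioxidants, cell wall, pollen and anther, defence, and ubiquitin had 2 members each, and auxin and lipid or wax 1 each. The photosynthesis list was also fixed as a marker of green tissue such as sepals, and the pollen and anther list as one of tissues next to the pistil. Whether the mix of tissues differed between groups was not tested. Each of 19 lists had 0 members in the table: CBF/DREB, other ERF, WRKY, MYB, NAC, bHLH with ICE1, bZIP and C2H2 factors, calcium signalling, MAP kinases, receptor kinases, abscisic acid, ethylene, jasmonate, gibberellin with brassinosteroid and cytokinin, sugar, phenylpropanoids, petal pigment and scent, and the circadian clock. For lists with at least 3 members fry from limma tested whether the members moved, on balance, to the same side, and its p was adjusted over these 5 lists.

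Named genes followed a rule. For each clone they were the 8 genes with the highest and the 8 with the lowest mean change over the 4 times among those past the F test. Added were the largest rise and fall at each time among genes past the threshold at that time. Genes without a Swiss-Prot name were passed over. For the clone difference they were genes past the threshold at most of the 5 times, then the 8 highest and 8 lowest by mean difference. The 10 genes with the smallest p were named for the interaction, and up to 4 members with the smallest p for each list. Genes outside the rule are said to have been chosen after their values were seen.

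Alternatives were a pseudocount of 0.1, no filter, centring on the median, the replicate number as a block, a fit of the compared groups alone, and leaving out each library in turn. Added after the data were seen were limma's voom weights on the recovered reads, centring on the genes outside the ribosomal list, removal of a trend with gene length, and a fit without the 2 libraries least like their group. The limma test was checked on simulated data for the NC 2 h comparison over 143 genes and 20 runs: 98.2% of changes of 1 and 78.5% of changes of 0.5 on the log2 scale were recovered, and 3.81% of calls were false. The simulated noise was independent between genes, and no library was shifted as a whole. These shares therefore do not cover real libraries in which all genes shift together. The recovery of reads was tested on 1430 simulated values and returned 1430 exactly. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.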

Results

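Transcript levels were compared between flowers of the frost-resistant clone CR and the frost-sensitive clone NC of Siberian apricot, before and during 2 h at -4 °C. The study asked which genes take part in the response to cold during flowering. The 143 abundant genes analysed here included 69 ribosomal protein genes, and single values ranged from 263 to 6019 FPKM. Each value rested on at least 2481 reads, which puts its counting error at no more than 2.01%.

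The overall level of the 143 genes was compared between groups. In CR the median FPKM was 1099 ± 169 (SD, n = 3) at 0 h, 848 ± 48.5 at 15 min, 890 ± 31.7 at 30 min, 931 ± 39.6 at 1 h and 1014 ± 54.0 at 2 h. In NC it was 763 ± 38.8 at 0 h, 762 ± 59.0 at 15 min, 759 ± 40.6 at 30 min, 782 ± 24.8 at 1 h and 616 ± 115 at 2 h. The reads of these genes took 17.5% ± 2.82 of the divisor in CR at 0 h and 13.5% ± 0.797 at 15 min, against 13.2% ± 0.820 in NC at 0 h, with a change of -2.23 percentage points in NC at 2 h. The largest difference, 5.28 percentage points between CR and NC at 2 h, had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and 0.26 after adjustment over 13 comparisons. Because all genes of a library can shift together, changes are also given relative to the median of all genes.

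**Figure D1:**
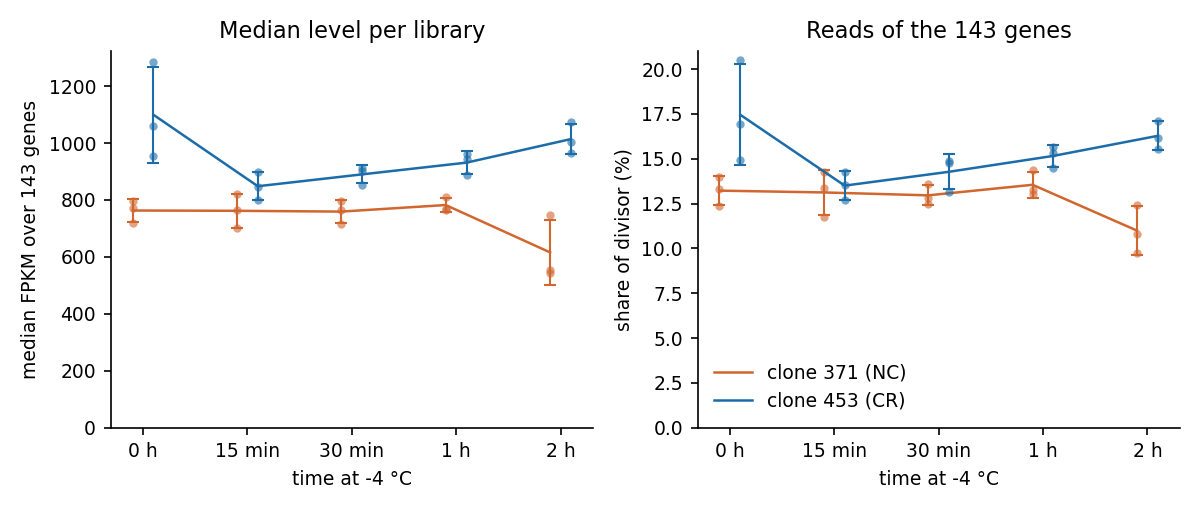
Median FPKM of the 143 genes (left) and their share of the implied divisor in percent (right) against time at -4 °C, with each library as a point and lines and bars for the mean and SD (n = 3). The CR median stands at 1099 FPKM at 0 h and 848 at 15 min, and the NC median at 763 at 0 h and 616 at 2 h.

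In the frost-sensitive clone NC, 7 genes rose and 90 fell after 2 h at -4 °C. ARG2, an auxin-induced protein with a late embryogenesis abundant domain (PaF106G0800029367.01, chromosome 8, 23489068 to 23489630), rose from 639 ± 92.8 to 3596 ± 2194 FPKM, a log2 change of 2.32 (SE 0.401, limma adjusted p = 9.92e-05). The metallothionein-like protein type 2, of a family of metal-binding proteins (PaF106G0600024567.01, chromosome 6, 23326826 to 23327992), rose from 783 ± 206 to 3258 ± 2082 FPKM, a change of 1.92 (SE 0.342, adjusted p = 9.92e-05). Polyubiquitin, the precursor of the tag for protein degradation, rose by 0.72 (adjusted p = 0.000579) from 745 ± 25.3 to 1256 ± 321 FPKM. The light-harvesting protein LHCII type I (PaF106G0300012505.01, chromosome 3, 15765392 to 15766500) had the largest fall, from 1618 ± 142 to 713 ± 174 FPKM, a change of -1.20 (SE 0.191, adjusted p = 9.92e-05). In these 4 genes the 3 libraries at 2 h all lay outside the range of the 3 at 0 h.

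The other genes that rose in NC at 2 h were the cysteine protease RD19A (0.81), the hydrophobic protein RCI2B (0.73), the non-specific lipid-transfer protein 1 (0.63) and thioredoxin H-type (0.39), with limma adjusted p of 0.00139, 0.0158, 0.00364 and 0.0266. The groups of RCI2B overlapped, since its NC 2 h libraries stood at 1008, 2083 and 1931 FPKM. Replicates also differed for ARG2, at 3026, 6019 and 1744 FPKM. Among the genes that fell were heat shock protein 90-2 (-0.74) and heat shock cognate 70 kDa protein (-0.76), both chaperones, tubulin beta-1 (-0.72) and tubulin alpha (-0.69), and chlorophyll a-b binding protein 151 (-0.84). Polyphenol oxidase, which oxidises phenols in browning tissue, fell from 4699 ± 647 to 3032 ± 165 FPKM (-0.62, adjusted p = 0.000722). The median change of all genes was -0.39, and -0.54 without NC_2h replicate 1. The median level of that library, 749 FPKM, lay within the range of the NC 0 h libraries (721 to 797). NC_2h replicates 2 and 3 stood at 544 and 555 FPKM, so the general fall was not seen in every library. Centring each library on its median took out a shift of -0.32, after which 21 genes were higher and 38 lower. Relative changes were 2.64 for ARG2, 2.24 for metallothionein, 1.05 for polyubiquitin, -0.88 for LHCII type I, -0.42 for heat shock protein 90-2 and -0.30 for polyphenol oxidase, each past the threshold.

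By group, 54 of 69 ribosomal protein genes fell in NC at 2 h (55 adjusted over the list alone), with a median change of -0.40 (limma fry adjusted p = 0.00364). Relative to the median 18 of them were lower and 2 higher (relative limma fry adjusted p = 0.0186). Ribosomal protein L3 had a change of -0.71 (adjusted p = 0.00015). Of the 8 photosynthesis genes 6 fell (6 adjusted over the list alone), with a median change of -0.52 (limma fry adjusted p = 0.00364), and 3 were lower and 1 higher relative to the median. The 6 include early nodulin-like protein 3 (-0.74), listed by its domain alone. The exception relative to the median was the photosystem II 10 kDa polypeptide (0.19, not past the threshold, and 0.52 relative, adjusted p = 0.0104). Of the 5 aquaporins, which are water channels, 3 fell (3 adjusted over the list alone, limma fry adjusted p = 0.0150, relative limma fry adjusted p = 0.0654): PIP1-2 (-0.69), PIP2-7 (-0.69) and TIP1-1 (-0.56). Relative to the median 2 aquaporins were higher and 2 lower (median of the list -0.23, mean 0.00), and TIP1-1 no longer passed (-0.23, adjusted p = 0.113). Of the 5 household genes 4 fell (4 adjusted over the list alone, limma fry adjusted p = 0.000701), among them elongation factor 1-alpha (PaF106G0600022515.01, -0.58). In the cold-regulated list ARG2 and RCI2B rose and heat shock protein 90-2 fell (2 and 1 adjusted over the list alone, limma fry adjusted p = 0.0890, relative limma fry adjusted p = 0.0187).

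In the smaller lists, thioredoxin H-type rose and L-ascorbate peroxidase had a change of -0.38 (-0.06 relative, not past the threshold). The cell wall gene xyloglucan endotransglucosylase/hydrolase protein 9 fell (-0.33, relative -0.01), as did the thaumatin-like defence protein (-0.47, relative -0.14) and the pollen-type Olee1-like protein (-0.50, relative -0.18). Adjusted over each list alone these counts were the same. Without NC_0h replicate 1 the count of 97 genes was 60, without NC_2h replicate 2 it was 62, without the length trend 64, and with the compared groups fitted alone 54. Of the 97 genes, 72 had groups that did not overlap, and over all genes 74 of 143 did not overlap, where chance gives 10% on average. Genes of a library shift together, so by chance this count can lie far from that average. It therefore does not exclude chance.

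Earlier times gave few calls in NC. At 15 min the lipid-transfer protein 1 rose from 631 ± 121 to 1030 ± 142 FPKM (0.71, SE 0.174, limma adjusted p = 0.0421). Oxygen-evolving enhancer protein 3 fell (-0.54, adjusted p = 0.0421), and so did the chlorophyll a-b binding protein CP26 (-0.46, adjusted p = 0.0421), which was chosen after its values were seen. In each of the 3 genes the groups did not overlap. Photosynthesis had 2 of 8 members lower (6 adjusted over the list alone, 5 relative to the median), with a median change of -0.45 (limma fry adjusted p = 0.0292). The count of 3 genes was 6 without NC_15min replicate 2, 1 without NC_0h replicate 1, and 0 without any of NC_0h replicates 2 and 3 and NC_15min replicates 1 and 3. It was 21 genes (13 higher, 8 lower) relative to the median, 23 with centring outside the ribosomal list, 16 without the length trend, and 1 with the replicate number as a block.

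At 30 min and 1 h limma called 0 genes in NC, with 19 and 1 genes at an unadjusted p under 0.05, and voom weights gave 0 and 0. Relative to the median 9 genes were higher and 12 lower at 30 min, and histone H1.2 was higher at 1 h (0.34). The counts were 20 at 30 min with centring outside the ribosomal list, 2 there without the length trend or without NC_30min replicate 2, and 1 at 1 h with the compared groups fitted alone. Over the 4 times the F test called 100 genes, 20 with a positive and 80 with a negative mean change, and 84 relative to the median (41 and 43). The highest mean changes were those of ARG2 (0.86), metallothionein (0.56), RD19A (0.50) and lipid-transfer protein 1 (0.44), followed by histone H1.2 (0.15), histone H4 (0.15) and the ribosomal proteins S21-2 (0.12) and P3-1 (0.09). The lowest were those of heat shock protein 90-2 (-0.39), L3 (-0.34) and polyphenol oxidase (-0.34). The count of 100 was 47 without NC_2h replicate 2 and 57 without NC_2h replicate 3.

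**Figure D2:**
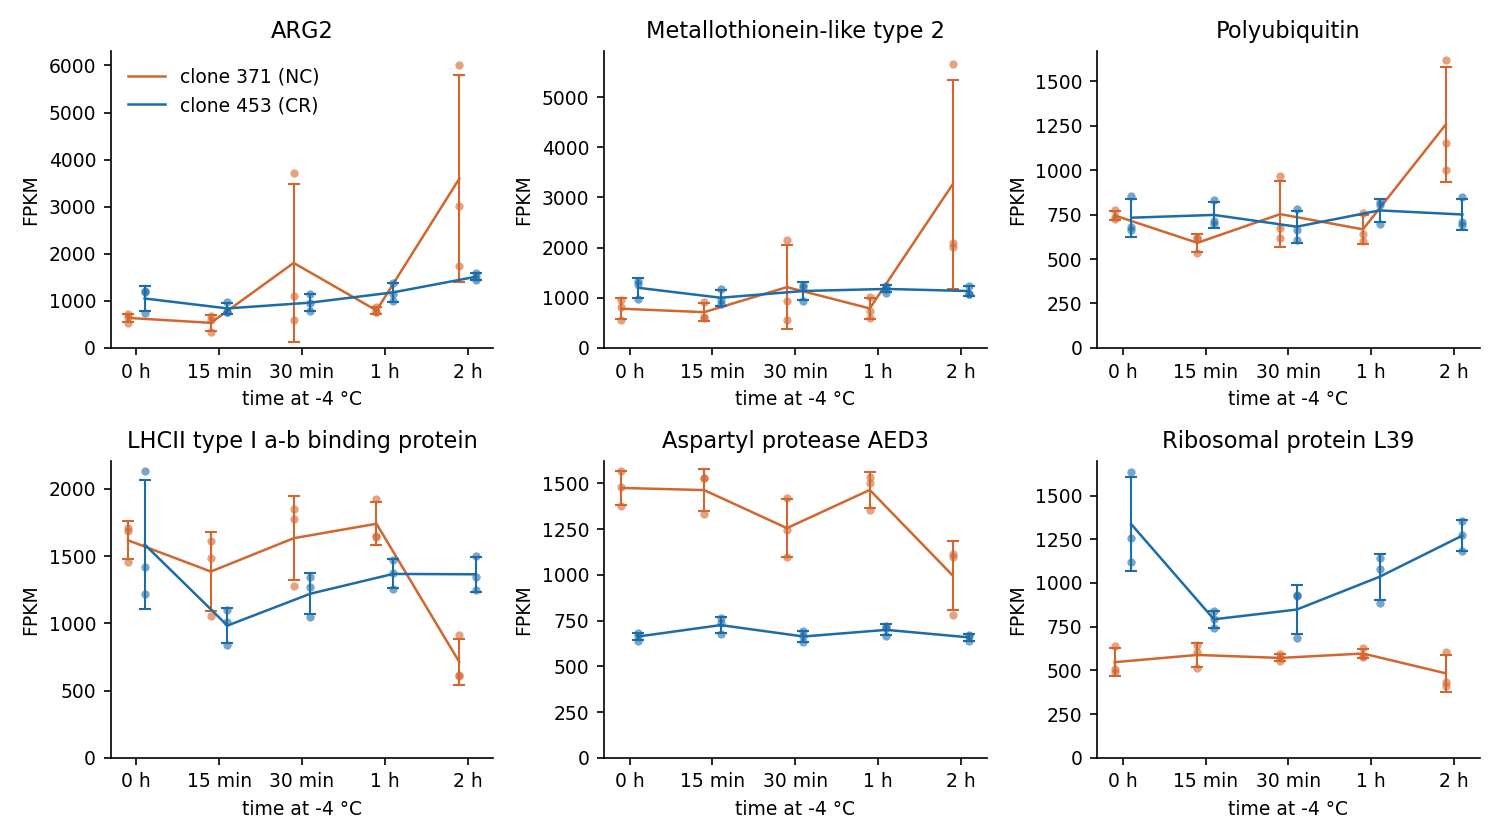
FPKM of 6 genes against time at -4 °C in both clones, with each library as a point and lines and bars for the mean and SD (n = 3). ARG2 and metallothionein reach 3596 and 3258 FPKM in NC at 2 h, LHCII type I falls to 713, and AED3 stays lower and L39 higher in CR than in NC.

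In the frost-resistant clone CR, 86 genes fell and 1 rose after 15 min. The gene that rose was adenosylhomocysteinase, an enzyme of the methylation cycle (PaF106G0100001906.01, chromosome 1, 12656257 to 12658231), from 698 ± 48.3 to 844 ± 23.8 FPKM (0.28, SE 0.106, limma adjusted p = 0.0272). The glycine-rich RNA-binding protein GRP1A (PaF106G0800031435.01, chromosome 8, 12699316 to 12700308) had the largest fall, from 3545 ± 1534 to 1560 ± 547 FPKM (-1.17, SE 0.365, adjusted p = 0.00921). It did not pass relative to the median (-0.81, adjusted p = 0.0643). Elongation factor 1-alpha (PaF106G0100000142.01) fell from 1014 ± 302 to 505 ± 66.0 FPKM (-0.97, adjusted p = 0.00054). In these 3 genes the groups did not overlap.

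Genes with the lowest mean change in CR included histone H4 (PaF106G0600024535.01, -0.72 at 15 min), histone H1.2 (-0.61), the mitochondrial ATP synthase 6 kDa subunit (-0.68), and the ribosomal proteins S30 (-0.80), S29 (PaF106G0800030893.01, -0.75), L36-1 (-0.71) and L31 (-0.64), each past the threshold at 15 min. The median change was -0.39. Centring took out a shift of -0.36, after which 19 genes were higher and 25 lower. Of the 69 ribosomal protein genes 50 fell (50 adjusted over the list alone), with a median of -0.43 (limma fry adjusted p = 0.0129), and 18 were lower and 6 higher relative to the median (relative limma fry adjusted p = 0.110). Of the 8 photosynthesis genes 5 fell (8 adjusted over the list alone, limma fry adjusted p = 0.0134, relative limma fry adjusted p = 0.521), among them LHCII type I (-0.66) and the photosystem II 10 kDa polypeptide (-0.52). For household genes 1 of 5 fell (1 adjusted over the list alone, limma fry adjusted p = 0.0634), while the direction turned relative to the median, with 3 higher and 1 lower (relative limma fry adjusted p = 0.0232). Of the aquaporins and the cold-regulated list 0 members passed in limma (0 adjusted over the list alone), and the limma fry adjusted p were 0.180 and 0.121. Both lists turned from lower to higher relative to the median (relative limma fry adjusted p = 0.0144 and 0.0974). Thioredoxin H-type (-0.51), ubiquitin-like protein 5 (-0.50), defensin-like protein 2 (-0.50) and xyloglucan endotransglucosylase/hydrolase protein 9 (-0.25) fell, the last of these not when adjusted over the list alone and with a relative change of 0.11. Of the heat shock proteins, pollen, lipid and auxin lists 0 members passed in limma, but relative to the median both heat shock proteins (0.32 and 0.33) and the Olee1-like protein (0.26) were higher.

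The number of falls in CR depended on single libraries. Without CR_0h replicate 1 the count of 87 genes at 15 min was 18, and without CR_15min replicate 2 it was 48. It was 54 with the compared groups fitted alone, 34 with centring outside the ribosomal list and 7 without the length trend. Groups did not overlap in 78 of the 87 genes and in 88 of all 143, where chance gives 10% on average. Because genes shift together, this does not exclude chance. At 30 min 48 genes fell, among them 33 ribosomal protein genes (39 adjusted over the list alone, limma fry adjusted p = 0.0604). Among genes past the threshold that had a name, the largest fall was that of L39, from 1337 ± 269 to 848 ± 141 FPKM (-0.65, SE 0.150, limma adjusted p = 0.0112). The lowest change of any of the 143 genes was -0.84. The median change at 30 min was -0.30, and after centring, which took out -0.29, adenosylhomocysteinase was higher (0.45) and 4 genes were lower: L39 (-0.36), the ATP synthase 6 kDa subunit (-0.31), and S30 (PaF106G0700027023.01, -0.25) and S19-1 (-0.17), the last 2 chosen after their values were seen. The count of 48 was 0 without CR_0h replicate 1, 2 without CR_30min replicate 1, 31 without CR_0h replicate 3 and 95 without CR_0h replicate 2. It was 11 with the compared groups fitted alone, 12 with centring outside the ribosomal list, and 0 in limma without the length trend or without the 2 libraries least like their group.

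At 1 h 9 genes fell in CR. Among those with a name, the largest fall was that of histone H2A.1 (-0.50, SE 0.135, limma adjusted p = 0.0306), in all 3 libraries. The lowest change of any of the 143 genes was -0.57. The median change was -0.25, and after centring, which took out -0.23, 0 genes passed in limma. The count of 9 was 71 without CR_0h replicate 2, 2 without CR_0h replicate 3, 1 without CR_1h replicate 3, and 0 without CR_0h replicate 1 or CR_1h replicates 1 or 2. It was 17 with the replicate number as a block, and 0 with the compared groups fitted alone or without the length trend. At 2 h limma and voom called 0 genes each, with 6 genes at an unadjusted p under 0.05 and 1 call with the compared groups fitted alone. The values for ARG2, metallothionein, polyubiquitin and LHCII type I were then 0.56, -0.07, 0.04 and -0.18 (adjusted p = 0.796, 0.920, 0.914 and 0.796). The F test over the 4 times called 50 genes, all with a negative mean change, and 23 relative to the median (8 higher, 15 lower). It called 14 without CR_0h replicate 1, 84 without CR_0h replicate 2, 19 without CR_15min replicate 2, 29 without CR_15min replicate 3, 15 with centring outside the ribosomal list and 6 without the length trend. Of these 50, the mean changes nearest to 0 were those of glycine-rich protein 2 (-0.22), histone H3.3 (-0.26), S18 (-0.27), S17 (-0.28) and L21-1 (-0.28).

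Comparing the clones, CR had higher levels of most of the 143 genes than NC, nearly all ribosomal protein genes among them, and lower levels of a small set. Averaged over the 5 times, 117 of 143 genes were higher and 10 lower in CR, with a median difference of 0.42. Centring took out a shift of 0.38, after which 59 genes were higher and 40 lower. The highest mean differences were those of the ribosomal proteins P3-1 (0.91, SE 0.091, limma adjusted p = 3.94e-10), L39 (0.89), L38 (0.87), L23A (0.85, adjusted p = 6.9e-14), L23 (0.83) and S27-2 (0.81). Elongation factor 1-alpha (PaF106G0100000142.01, 0.83) and the microtubule-associated SPIRAL1-like 1 (0.81) followed. L39 stood at 1337 ± 269 FPKM in CR and 547 ± 80.7 in NC at 0 h, and at 1271 ± 86.9 and 483 ± 107 at 2 h. Each of these 8 genes was also higher relative to the median, from 0.43 for S27-2 to 0.54 for P3-1.

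Aspartyl protease AED3 (PaF106G0200007260.01, chromosome 2, 4037081 to 4039588) was lower in all 15 CR libraries than in any of the 15 NC libraries, with 663 ± 20.9 FPKM in CR and 1476 ± 93.7 in NC at 0 h, and a mean difference of -0.94 (SE 0.052, adjusted p = 8.11e-15). S-adenosylmethionine decarboxylase, which commits methionine to polyamine synthesis, was lower in CR at both of its genes (PaF106G0300011722.01, -0.66, and PaF106G0100003565.01, -0.37). The aquaporin PIP2-5 was lower too (-0.59, adjusted p = 1.72e-10), with 858 ± 74.3 FPKM in CR and 1246 ± 7.82 in NC at 0 h. The lowest mean difference was that of a gene named after ART3, a yeast open reading frame antisense to ribosomal RNA (-1.22, SE 0.167, adjusted p = 1.23e-07), with 560 ± 79.9 FPKM in CR and 1176 ± 160 in NC at 0 h. This difference ran opposite to that of the ribosomal protein genes. Histone H1.2 differed by 0.00 (adjusted p = 0.981), but by -0.37 relative to the median (adjusted p = 2.63e-09). In its mean of 0.00 differences of opposite sign cancel. This gene passed the threshold at 4 of the 5 times, and its change to 1 h in CR minus that in NC was -0.85.

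Of the 69 ribosomal protein genes 68 were higher in CR by the mean over 5 times (68 adjusted over the list alone), with a median of 0.52 (limma fry adjusted p = 1.25e-08). Relative to the median 47 were higher and 6 lower (relative limma fry adjusted p = 2.05e-10). S15-4 (PaF106G0600025643.01) went from 0.28 to -0.10, not past the threshold. Ribosomal protein genes were shorter (median 775 bases) than the other genes (1113 bases). For a slope on log2 length, each gene's log2 level was taken as a deviation from its mean over all libraries. This slope was positive in NC at every time, from 0.08 at 2 h to 0.22 at 0 h. In CR it was negative, from -0.25 at 0 h to -0.04 at 15 min. Such slopes cancel over all libraries, so their signs say nothing alone and only differences between groups can be read. Shorter genes thus stood higher against longer ones in CR than in NC. At 0 h the clone difference ran with length within ribosomal (Pearson r = -0.65) and within other genes (-0.60). The ribosomal difference relative to the median therefore cannot be told apart from length here. By time, 65 of the ribosomal protein genes were higher at 0 h, 12 at 15 min, 41 at 30 min, 46 at 1 h and 69 at 2 h (65, 12, 44, 47 and 69 adjusted over the list alone). For photosynthesis 7 of 8 were higher (7 adjusted over the list alone, limma fry adjusted p = 0.000137), among them the photosystem II 10 kDa polypeptide (0.44). The member with the largest difference, early nodulin-like protein 3 (0.55), is a cell-surface phytocyanin that matched the list only by its plastocyanin-like domain and is no photosynthesis gene. The direction of that list turned relative to the median, where 1 was higher and 4 lower (relative limma fry adjusted p = 0.0419), and oxygen-evolving enhancer protein 1 went from 0.37 to -0.01. Aquaporins were split, with 2 higher and 2 lower (2 and 2 adjusted over the list alone, limma fry adjusted p = 0.0950), but 4 of 5 were lower relative to the median (relative limma fry adjusted p = 2.14e-12), where PIP2-7 went from 0.38 to 0.00. Ribosomal protein genes weigh on this median and were mostly higher in CR. A list that turns lower against it is therefore lower against a largely ribosomal reference.

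Of the household genes 3 of 5 were higher (3 adjusted over the list alone, limma fry adjusted p = 4.7e-06), and relative to the median 1 was higher and 2 lower (relative limma fry adjusted p = 0.00225), with tubulin beta-1 and alpha moving from 0.35 and 0.37 to -0.03 and -0.01. In the cold-regulated list RCI2B (0.32) and heat shock protein 90-2 (0.20) were higher (2 adjusted over the list alone, limma fry adjusted p = 0.000343), and relative to the median the direction turned (relative limma fry adjusted p = 0.00171), with values of -0.05 and -0.18, the latter past the threshold. ARG2, the only member of the auxin list, differed by 0.08 (adjusted p = 0.688). Heat shock cognate 70 kDa protein (0.38, 0.01 relative), thioredoxin H-type (0.38, 0.01 relative), lipid-transfer protein 1 (0.49, 0.11 relative) and xyloglucan endotransglucosylase/hydrolase protein 9 (0.45, 0.07 relative) were higher, but not past the threshold relative to the median. L-ascorbate peroxidase turned from 0.22 to -0.16, past the threshold on both sides. The thaumatin-like protein went from 0.30 to -0.08 and defensin-like protein 2 from 0.32 to -0.06, neither past the threshold relative to the median. Arabinogalactan protein 31, in the cell wall and the pollen lists, was lower (-0.13, adjusted p = 0.0397), and ubiquitin-like protein 5 was higher (0.77, 0.40 relative). Polyubiquitin differed by -0.06 (adjusted p = 0.392), and the Olee1-like protein was higher by 0.20 and lower relative to the median (-0.18).

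**Figure D3:**
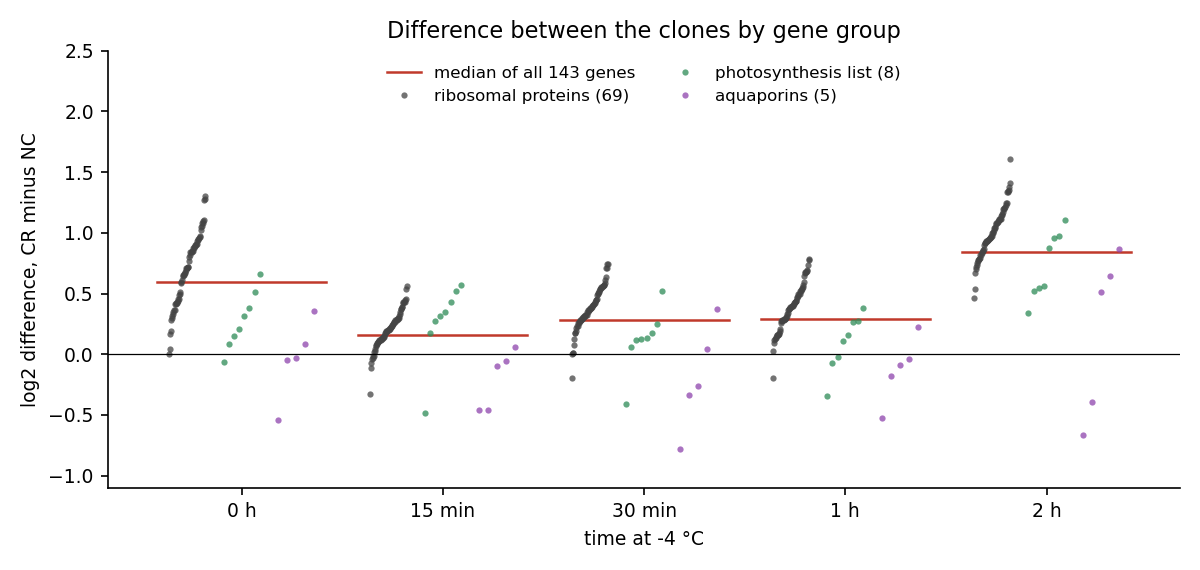
Log2 difference between CR and NC (vertical axis) at each time at -4 °C for the genes of 3 lists, each gene as a point, with the median of all 143 genes as a red line. The ribosomal median is 0.71 at 0 h and 1.00 at 2 h, and all 5 aquaporins lie below the red line at 0 h.

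At single times CR differed from NC in 107 genes at 0 h (101 higher, 6 lower), 21 at 15 min (16 and 5), 66 at 30 min (57 and 9), 68 at 1 h (59 and 9) and 129 at 2 h (121 and 8). The median differences were 0.59, 0.16, 0.28, 0.29 and 0.84. Centring took out shifts of 0.52, 0.16, 0.23, 0.25 and 0.73, after which the higher and lower counts were 53 and 39 at 0 h, 15 and 19 at 15 min, 34 and 23 at 30 min, 30 and 24 at 1 h, and 56 and 34 at 2 h. Of 78 genes past the threshold at 3 or more times, 73 were higher and 5 lower in CR by the mean over 5 times, and 16 passed at all 5 times. The 73 include histone H1.2, whose mean difference was 0.00. Those 5 lower were AED3, PIP2-5, ART3 and both S-adenosylmethionine decarboxylase genes. At 2 h ARG2 (-1.07, limma adjusted p = 0.0144), metallothionein (-1.35), RD19A (-0.92), polyubiquitin (-0.72) and the aquaporin PIP1-4 (-0.39, chosen after its values were seen) were also lower in CR, in all 3 libraries of each. Groups did not overlap in 105, 54, 79, 106 and 129 genes, where chance gives 10% on average. Because genes shift together, these counts do not exclude chance. The count at 15 min was 5 without CR_15min replicate 1 and 6 without NC_15min replicate 3, and that at 30 min was 37 without NC_30min replicate 3. The count at 1 h was 30 without CR_1h replicate 1, 36 without NC_1h replicate 3, 40 without NC_1h replicate 1, 41 without CR_1h replicate 3 and 106 with the compared groups fitted alone. Without the length trend the counts were 67 at 0 h and 45 at 15 min, and without the 2 libraries least like their group 38 at 30 min.

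**Figure D4:**
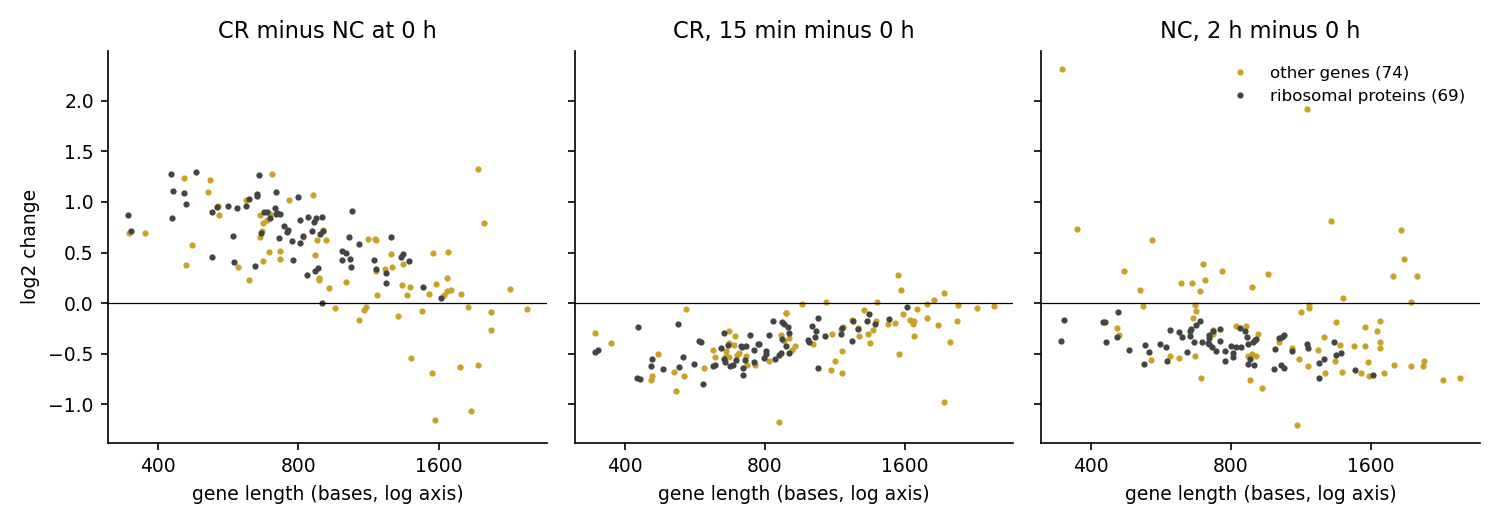
Log2 change of each gene (vertical axis) against its length in bases (log axis) for CR against NC at 0 h, CR at 15 min and NC at 2 h, with ribosomal protein genes dark and other genes light. Shorter genes are higher in CR at 0 h (Pearson r = -0.66 across genes) and lower in CR after 15 min (r = 0.58).

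The change with time differed between the clones in 112 genes by the interaction test, in 70 relative to the median and in 33 without the length trend. At 15 min the changes of 61 genes differed, 60 of them lower in CR, but relative to the median 28 were higher and 39 lower. Those lower included elongation factor 1-alpha (PaF106G0100000142.01, -1.27, SE 0.240, limma adjusted p = 0.000887), the ATP synthase 6 kDa subunit (-1.04) and ubiquitin-like protein 5 (-0.83). Heat shock protein 90-2 (0.27, 0.63 relative) and L3 (0.18, 0.54 relative) were higher past the threshold only relative to the median. Adenosylhomocysteinase was the 1 gene higher in both (0.50, adjusted p = 0.0112). At 2 h 24 genes differed, 19 higher and 5 lower in CR, and relative to the median 23 were higher and 12 lower. The 5 lower were metallothionein (-1.99, SE 0.483, adjusted p = 0.0117), ARG2 (-1.76, SE 0.567, adjusted p = 0.0325), polyubiquitin (-0.69, adjusted p = 0.0325), thioredoxin H-type (-0.63, adjusted p = 0.0401) and histidine-containing phosphotransfer protein 1 (-0.58, adjusted p = 0.0325), the last chosen after its values were seen. Higher were LHCII type I (1.02, SE 0.270, adjusted p = 0.0159), heat shock cognate 70 kDa protein (0.79), heat shock protein 90-2 (0.68) and S-adenosylmethionine decarboxylase (PaF106G0100003565.01, 0.77). RCI2B (-0.92, adjusted p = 0.0693) and RD19A (-0.78, adjusted p = 0.0518) did not pass, though RD19A did relative to the median (adjusted p = 0.0277), where it was also lower, as did lipid-transfer protein 1 (-0.74) and ubiquitin-like protein 5 (-0.70).

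At 30 min 13 genes differed in their change, with adenosylhomocysteinase higher in CR (0.50) and 12 lower, but relative to the median the balance turned to 17 higher, among them tubulin alpha (0.58) and AED3 (0.52), and 10 lower. At 1 h only histone H1.2 passed (-0.85, adjusted p = 0.0255). Among lists, 37 of 69 ribosomal protein genes had a lower change in CR at 15 min (40 adjusted over the list alone, limma fry adjusted p = 0.0556). Relative to the median 29 were lower and 9 higher (relative limma fry adjusted p = 0.0124). Household, photosynthesis and cold-regulated genes (relative limma fry adjusted p = 0.0124 each) and aquaporins (0.0243) went the other way relative to the median. Before centring their limma fry adjusted p ran from 0.573 to 0.990. The ribosomal result is therefore not particular to that list. At 2 h none of the 5 lists passed fry, the smallest adjusted p being 0.0889 for household genes and 0.0795 relative to the median. Both heat shock proteins had a higher change in CR at 2 h (2 adjusted over the list alone).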

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

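The tests of scaling within comparisons, of gene length and of single libraries were chosen after the results had been seen, whereas the counts over other splits and the test of the common shift were chosen before the data were examined. In 112 genes the change with time at -4 °C differed between the clones by the interaction test, which is what singled them out, and the count was 33 without the length trend. The 10 named genes with the smallest p (F test in limma, adjusted p from 0.0013 to 0.00146) are given as the change in CR minus the change in NC. At 15 min the differences were -0.91 for S29 (PaF106G0100004968.01), -0.82 for L38, -1.04 for the ATP synthase 6 kDa subunit, -0.86 for S21-2, -0.80 for S27-2, -1.27 for elongation factor 1-alpha (PaF106G0100000142.01), -0.70 for S16 (PaF106G0800031042.01) and -0.69 for L35. Histone H1.2 differed by -0.91 at 30 min, and LHCII type I by 1.02 at 2 h.

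With 3 libraries in each group there are 10 ways to split the libraries of a comparison, which are too few to exclude chance. In CR against 0 h, the real split called 87 genes at 15 min (highest other split 57), 48 at 30 min (3) and 9 at 1 h (0), each reached by 1 split. In NC at 15 min it called 3 (0), reached by 1 split, and in NC at 2 h 97 (101), reached by 2. For CR at 2 h and NC at 30 min and 1 h all 10 splits called 0 genes. Between the clones the real split called 107 genes at 0 h (70), 21 at 15 min (0), 66 at 30 min (0), 68 at 1 h (0) and 129 at 2 h (89), each reached by 1 split. Over 100 splits, the real one included, 1 reached the 50 genes of the CR time course (highest other 48) and 1 the 100 of NC (94). Both shares lie under the 0.05 level, though other splits came close to these counts. For the interaction 4 splits reached the 112 genes (128). Those splits swapped the clone labels within each time, which also mixes the difference between the clones. They therefore cannot decide whether the interaction count arose by chance.

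Of the genes that differed between the clones at 0 h, 101 were higher and 6 lower in CR, with a median difference of 0.59. A single scaling factor per library is argued against as the whole cause of differences between genes, since 92 genes passed after centring. The common shift of 0.59 cannot be told apart from the authors' divisor, because the genes that set it were not used here. The difference ran with gene length (Pearson r = -0.66 across genes, which are not independent). Without the length trend 47 of the 92 genes kept their direction and significance, and 79 kept their direction. The median size over all 92 was then 0.20 (median SE 0.0781), against 0.42 (0.0841) before. Length may thus account for part of the difference, and the rest stays open. A difference between the genotypes, the one the design offers, remains a hypothesis.

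In NC at 2 h, where 90 genes fell and ARG2 and metallothionein rose, a single library is argued against as the whole cause of the falls. Of the 90 falls, 55 remained past the threshold without NC_0h replicate 1, 56 without NC_2h replicate 2 and 59 without NC_2h replicate 3. The 90 were selected as falling, and the count of 97 genes was 54 with the compared groups fitted alone. Over all 143 genes the median change was -0.29 (median SE 0.151) without NC_2h replicate 2 and -0.54 (0.137) without NC_2h replicate 1, against -0.39 (0.139). With 3 libraries per group the share of single libraries in the common fall therefore cannot be told apart. Centring left 59 genes, which argues against a single scaling factor per library as the whole cause of differences between genes. Without a length trend 49 of these 59 remained, which argues against that trend as the whole cause. The trend removed was fitted over all genes together, where the change ran with length at Pearson r = -0.21. Within ribosomal genes r was -0.53 and within other genes -0.32, so length within these classes is not fully covered. The common shift of -0.39 was not tested against the divisor. The design offers 2 h at -4 °C against 0 h, with no flowers held for 2 h at another temperature. A response of the frost-sensitive clone to cold therefore remains a hypothesis for the genes that changed relative to the median. Elapsed time and handling cannot be told apart from it.

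In CR at 15 min 86 genes fell, and groups did not overlap in 78 of the 87 called genes. Without CR_0h replicate 1, 18 of the 86 falls remained past the threshold (48 without CR_15min replicate 2), and the median change of the 86, which were selected as falling, was -0.37 (median SE 0.150) against -0.51 (0.144). Over all 143 genes the median change was -0.26 (0.144) with 129 lower, against -0.39 (0.139) with 137 lower, so with 3 libraries per group the share of this library cannot be told apart. Centring left 44 genes, which argues against a single scaling factor per library as the whole cause of differences between genes. Without the length trend 7 of the 44 remained past the threshold and 42 kept their direction. The median size of the change over all 44 was then 0.14 (median SE 0.0706), against 0.26 (0.0811) before, so length may account for part of it. A rapid response to -4 °C in CR was not tested and remains open. No flowers were held for 15 min at another temperature, so elapsed time and handling cannot be told apart from it.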

How the results depend on the processing

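The replicate block, the fit of the compared groups alone, centring on the median, the pseudocount, the filter and leaving out each library were chosen before the data were examined. The voom weights, centring on genes outside the ribosomal list, removal of the length trend and the fit without 2 libraries were chosen after. Voom weights left all counts within 1.5 times. So did a pseudocount of 0.1 and no filter, but these settings could hardly move a count. The filter had removed 0 genes, and the lowest FPKM was 263. Where a count or direction moved, the cause was not tested.

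With libraries centred on their median, counts were 44 for CR at 15 min (main 87), 5 at 30 min (48), 0 at 1 h (9), 21 for NC at 15 min (3), 21 at 30 min (0), 1 at 1 h (0) and 59 at 2 h (97). They were 34 for CR against NC at 15 min (21), 23 for the CR time course (50) and 70 for the interaction (112). Higher and lower counts in the interaction went from 23 and 89 to 29 and 41, and for the mean difference between clones from 117 and 10 to 59 and 40. Centring on genes outside the ribosomal list gave 34 for CR at 15 min, 12 at 30 min, 23 for NC at 15 min, 20 at 30 min and 15 for the CR time course. Without the length trend, counts were 7, 0 and 0 for CR at 15 min, 30 min and 1 h, 16, 2 and 64 for NC at 15 min, 30 min and 2 h, 67 and 45 for CR against NC at 0 h and 15 min, 6 for the CR time course and 33 for the interaction. With the groups compared alone they were 54, 11, 0 and 1 for CR at 15 min, 30 min, 1 h and 2 h, 1 and 54 for NC at 1 h and 2 h, and 106 for CR against NC at 1 h. With the replicate block they were 17 for CR at 1 h and 1 for NC at 15 min. The replicate numbers were not taken as pairs, because the labels give no shared origin and only 59 of 135 pairs with the same number, not all, had correlated deviations above 0.1. The mean correlation was 0.0507 for the same number and -0.0251 for different numbers, and 15 of 30 libraries correlated best with their own number, so the numbers may carry some shared variation. Without NC_30min replicate 3 and CR_30min replicate 1, the 2 least like their group, counts were 0 for CR at 30 min and 38 for CR against NC at 30 min.

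Leaving out each library in turn gave 18 to 106 genes for CR at 15 min, 0 to 95 at 30 min, 0 to 71 at 1 h and 0 to 0 at 2 h. In NC it gave 0 to 6, 0 to 2, 0 to 0 and 60 to 116. Between the clones it gave 88 to 112 at 0 h, 5 to 25 at 15 min, 37 to 76 at 30 min, 30 to 60 at 1 h and 124 to 132 at 2 h. The time courses ranged from 14 to 84 in CR and from 47 to 118 in NC, and the interaction from 92 to 123.

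Among named genes, the mean clone difference reversed under centring for S15-4 (PaF106G0600025643.01, -0.10), the thaumatin-like protein (PaF106G0500021222.01, -0.0786), L-ascorbate peroxidase (PaF106G0600022457.01, -0.16), oxygen-evolving enhancer protein 1 (PaF106G0700027362.01, -0.0114), defensin-like protein 2 (PaF106G0100004036.01, -0.0607), PIP2-7 (PaF106G0800030605.01, -5e-04), tubulin beta-1 (PaF106G0600022131.01, -0.0296) and tubulin alpha (PaF106G0100006249.01, -0.0076). Reversed here means a change of sign, whether or not the new value passed the threshold. Of these 8 genes only L-ascorbate peroxidase passed on the other side (limma adjusted p = 1.34e-05). For the others the limma adjusted p ran from 0.0641 to 0.994, so their differences were lost and not turned. L-ascorbate peroxidase (PaF106G0600022457.01) also changed sign with centring outside the ribosomal list (-0.0062, limma adjusted p = 0.875). Without the length trend the difference reversed for S15-4 (PaF106G0600025643.01, -0.11), thioredoxin H-type (PaF106G0100004393.01, -0.0751), lipid-transfer protein 1 (PaF106G0600025011.01, -0.0637) and the photosystem II 10 kDa polypeptide (PaF106G0400016541.01, -0.0378), and the 15 min change of S17 (PaF106G0200007773.01) in CR was 0.0604. The 5 results that changed sign without the length trend were not past the threshold there (limma adjusted p from 0.0570 to 0.630). Of named gene results, 58 kept direction and side of the threshold under centring, 20 were weaker and 8 reversed. Without the length trend these numbers were 55, 26 and 5. With centring on genes outside the ribosomal list they were 67, 18 and 1. Counting error was at most 2.01% of a value if reads are independent, which was not measured. On that assumption depth limits none of these results.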

Other observations

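The groups in this part were chosen after the gene values had been seen. Chromatin proteins, 10 genes for histones H1.2, H2A, H2A.1, H3.2, H3.3, 3 genes for H4 and 2 for high mobility group B protein 2, were all lower in CR after 15 min than at 0 h by limma, with a median change of -0.55, and 3 of them also relative to the median of all genes. In CR 5 of them were lower at 30 min, 4 at 1 h and 0 at 2 h, where the median was -0.22. In NC 0 passed before 2 h, when 2 were lower. CR exceeded NC in 9 of the 10 at 0 h and in 9 at 2 h. Relative to the median 3 were higher and 0 lower at 0 h, and 2 were higher and 4 lower at 2 h. At 30 min 3 were higher and 2 lower in CR, and at 1 h 1 was higher and 2 lower. Relative to the median 0 were higher and 2 lower at each of these times.

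Adenosylhomocysteinase and 2 genes for S-adenosylmethionine decarboxylase, which draw on the methyl donor S-adenosylmethionine or its product, were compared between the clones. By limma 3 of 3 were lower in CR at 0 h, 2 at 15 min, 2 at 30 min, 3 at 1 h and 1 at 2 h, and all 3 were lower at each time relative to the median. At 2 h PaF106G0100003565.01 differed by 0.16, not past the threshold and on the other side. The median differences were -0.63, -0.42, -0.46, -0.50 and -0.16. Enolase, aldolase 1, the glyceraldehyde-3-phosphate dehydrogenase GAPC2 and malate dehydrogenase fell in NC at 2 h, 4 of 4 with a median of -0.43, but 0 of 4 relative to the median of all genes. Of 3 glycine-rich proteins 3 were higher in CR than in NC at 0 h and 3 at 2 h, and relative to the median 0 and 1.

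Among NC libraries at 30 min, replicate 3 stood apart, with a mean correlation of 0.832 with its group mates. ARG2 (PaF106G0800029367.01) was 1109, 594 and 3714 FPKM in replicates 1, 2 and 3, metallothionein 929, 551 and 2159, RD19A 741, 592 and 1450, polyubiquitin 676, 617 and 965, and LHCII type I 1776, 1848 and 1276.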
